A study of Mus musculus with 6 samples.

How the data were processed

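Polyadenylated RNA libraries (KAPA mRNA HyperPrep, per the labels' protocols) were made from total RNA of 4T1 cells, a mouse mammary adenocarcinoma line, with a control or an HSF1-directed hairpin, 3 libraries each. Reads were handled with STAR and featureCounts against the mouse build mm10, per the submitters' processing notes; versions, annotation, strand setting and the treatment of reads shared between genes are not given in the sources used here. The values deposited by the authors are RPKM (reads per kilobase of gene, scaled to library size) for 24421 genes with gene lengths and positions, per the file headers. Whether the replicates were separate cultures is not stated in the labels, so p-values measure the spread between these libraries, which may be technical. Antisense and overlapping genes, and close gene copies, may share reads. No column of an unmatched sample was present (0).

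RPKM multiplied by gene length and divided by the value of 1 read gave whole reads for 100% of values within a tolerance of 0.001, so totals could be computed: 23750025 to 36903175 reads per library. Read totals and floors (3 reads) cover counting error only. A spreadsheet program had turned 27 gene symbols into dates; 25 were restored from their positions, and 2 remained unresolved and were kept under row names of their own. Of all symbols, 95.7% were found in GENCODE M21. No mitochondrial gene was listed (0).

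Groups and replicate numbers came from the sample titles. Values were transformed to log2(RPKM + 0.5); fold changes are on that scale and understate the change of low genes. Genes with at least 0.5 RPKM in 3 or more of 6 libraries (11386) were tested with limma 3.58.1 in R 4.3.3 (a linear model per gene, empirical Bayes with a variance trend), shHSF1 minus shCTL without a block, and Benjamini-Hochberg adjustment at 0.05. Gene lists with at least 5 tested members (24 of 28) were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, which asks whether members move on balance one way and compares them with no other genes. With 6 libraries or fewer, camera with an estimated correlation has few degrees of freedom and little power. That version called no list even for replicate 1 against replicates 2 and 3, where 4051 genes passed limma. A list that it did not call is thus not argued against. Exact two-sided permutation tests were run for Hsf1 and Ccl5. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.

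The design, the alternatives, the lists and the rule for named genes were fixed before the data were examined. Named were Hsf1 and Ccl5; up to 10 genes with the largest rise and 10 with the largest fall among those past the test, without overlap between groups, with a mean of at least 1 RPKM in the higher group; and from each list up to 3 members past the test, or else the 2 with the smallest p as values only. Other genes named, such as abundant list members and those called under the block, were chosen after their values were seen.

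The replicate numbers were checked for pairing before calls were compared. Across genes, which are not independent replicates, the deviations from the group means of same-numbered libraries correlated at 0.58, 0.18 and 0.68. All were above 0.1, and by that rule the numbers were taken to pair the samples. The labels do not say what a number shares. shCTL replicate 2 correlated more highly with shHSF1 replicate 3 (0.51) than with its own number, as did shHSF1 replicate 2 with shCTL replicate 3 (0.24). Deviations within a group cancel out, so with replicate 1 apart in both groups the other replicates deviate together however they are paired. The rule thus shows that replicate 1 differs in both groups, and cannot show that numbers 2 and 3 pair samples. Blocked values are printed where they change a call or move a count of calls by over 1.5 times. No 2 libraries were alike within sampling noise: chi-square per degree of freedom over genes was at least 21.6 for every pair of libraries.

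Alternatives were other pseudocounts (0.1 and 1), other filters, median-of-ratios, quantile and equal-sum scaling, no variance trend, library weights, the replicate block, and each library left out in turn. Added after the data were seen were both replicate 1 libraries left out, replicate 1 as a batch covariate, and voom on the whole reads with and without the block. The code was tested on simulated data for this comparison, over 11386 genes with a spread shared by replicate number: without a block it recovered 0% of 1.5-fold, 13.4% of 2-fold and 78.8% of 4-fold changes, with 3.2% of calls false, and with the block 16.4%, 71.6% and 93.9%, with 11.9% of calls false. The single-cell and human cell line data that the series design mentions were not analysed here.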

Results

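Messenger RNA was sequenced from 4T1 cells, a mouse mammary carcinoma line grown in culture, carrying either a control short hairpin RNA (shCTL) or one directed against HSF1 (shHSF1), the transcription factor that drives the heat shock response. Each group held 3 libraries, numbered as replicates 1 to 3. Reads assigned to genes came to 24628758, 23750025 and 27156162 for shCTL replicates 1 to 3, and to 24485872, 36903175 and 28658163 for the libraries labelled shHSF1. At that depth 3 reads on a gene of 2 kb stood for between 0.041 and 0.063 RPKM. Of 24421 genes, 11386 passed the filter on low values and were tested. The 10 most abundant genes took 9.41% of the reads in shCTL replicate 1 and between 5.46% and 7.49% in the other 5 libraries.

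Both replicate 1 libraries stood apart from the other 4. The first principal component carried 53.8% of the variance and placed them at −47.0 and −38.5, against 13.4 to 30.7 for replicates 2 and 3, while the second carried 26.0% and placed all 3 shCTL libraries below 0 and all 3 shHSF1 libraries above it. Gene counts, the lists called, Hsf1 and Ccl5 are therefore also given without both replicate 1 libraries (2 against 2, added after the data were seen). Some values are given for the replicate 1 pair alone, which has 1 library per group and no test.

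**Figure D1:**
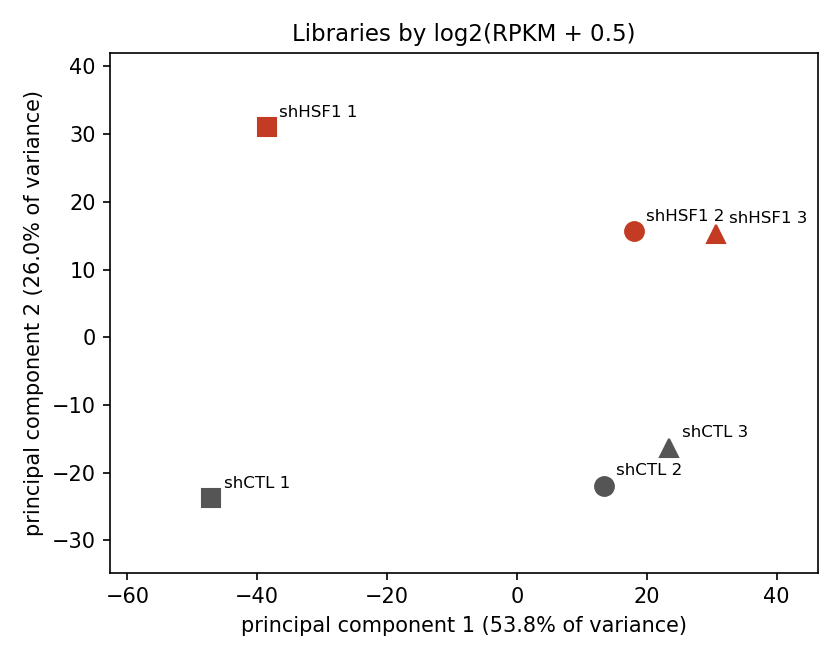
Each point is 1 library, placed by its first and second principal component (53.8% and 26.0% of the variance of log2(RPKM + 0.5)); grey marks shCTL, red shHSF1, and the marker shape the replicate number. Both replicate 1 libraries lie at −38.5 or below on the first component, and the groups part on the second.

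The first comparison asked whether the hairpin lowered its target. Hsf1 (chromosome 15, 76477445 to 76500972, plus strand, mm10) stood at 18.4, 20.3 and 20.1 RPKM in shCTL replicates 1 to 3, and at 23.2, 13.8 and 15.4 RPKM in the libraries labelled shHSF1 replicates 1 to 3. The group means were 19.6 ± 1.00 and 17.4 ± 5.06 RPKM (SD, n = 3 each). Hsf1 was thus 32.1% and 23.4% below the same-numbered control in replicates 2 and 3, and 25.9% above it in the library labelled shHSF1 replicate 1. The log2 difference over all 6 libraries was −0.20 (SE 0.21, limma adjusted p = 0.810), and an exact two-sided permutation test gave p = 0.4, where 0.1 is the smallest value 3 against 3 can give. Without both replicate 1 libraries the difference was −0.46 (SE 0.10, limma adjusted p = 0.0433). The adjusted p ran from 0.000789, with library weights that did not converge, to 0.986 over all alternatives. Because the target transcript was not lower in the library labelled shHSF1 replicate 1, every direction that follows rests on that label as given.

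The series title names Ccl5, a chemokine that attracts T cells and other leukocytes, so its level in the cultured tumour cells was the next question. Ccl5 (chromosome 11, 83525779 to 83530518, minus strand) was scarce in shCTL, at 1.45, 0.872 and 2.29 RPKM (1.54 ± 0.712, SD, n = 3), and stood at 4.00, 7.86 and 7.16 RPKM (6.34 ± 2.06) in the libraries labelled shHSF1. These values rest on 19, 11 and 33 reads against 52, 154 and 109. The ratio of the means was 4.12, and the same-numbered ratios were 2.75, 9.01 and 3.13, so all 3 pairs went the same way and the groups did not overlap. The log2 difference was 1.76 (SE 0.35), with a limma adjusted p of 0.168 over all genes tested and 0.015 adjusted over the list alone for the chemokines. The exact two-sided permutation p was 0.1, the smallest possible. Without both replicate 1 libraries the log2 difference was 2.03 (SE 0.32, limma adjusted p = 0.0226), and with replicate 1 as a batch covariate the adjusted p was 0.0388. Ccl5 did not pass with the planned replicate block (limma adjusted p = 0.0921). Over all alternatives the adjusted p ran from 0.000126, with library weights that did not converge, to 0.645.

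**Figure D2:**
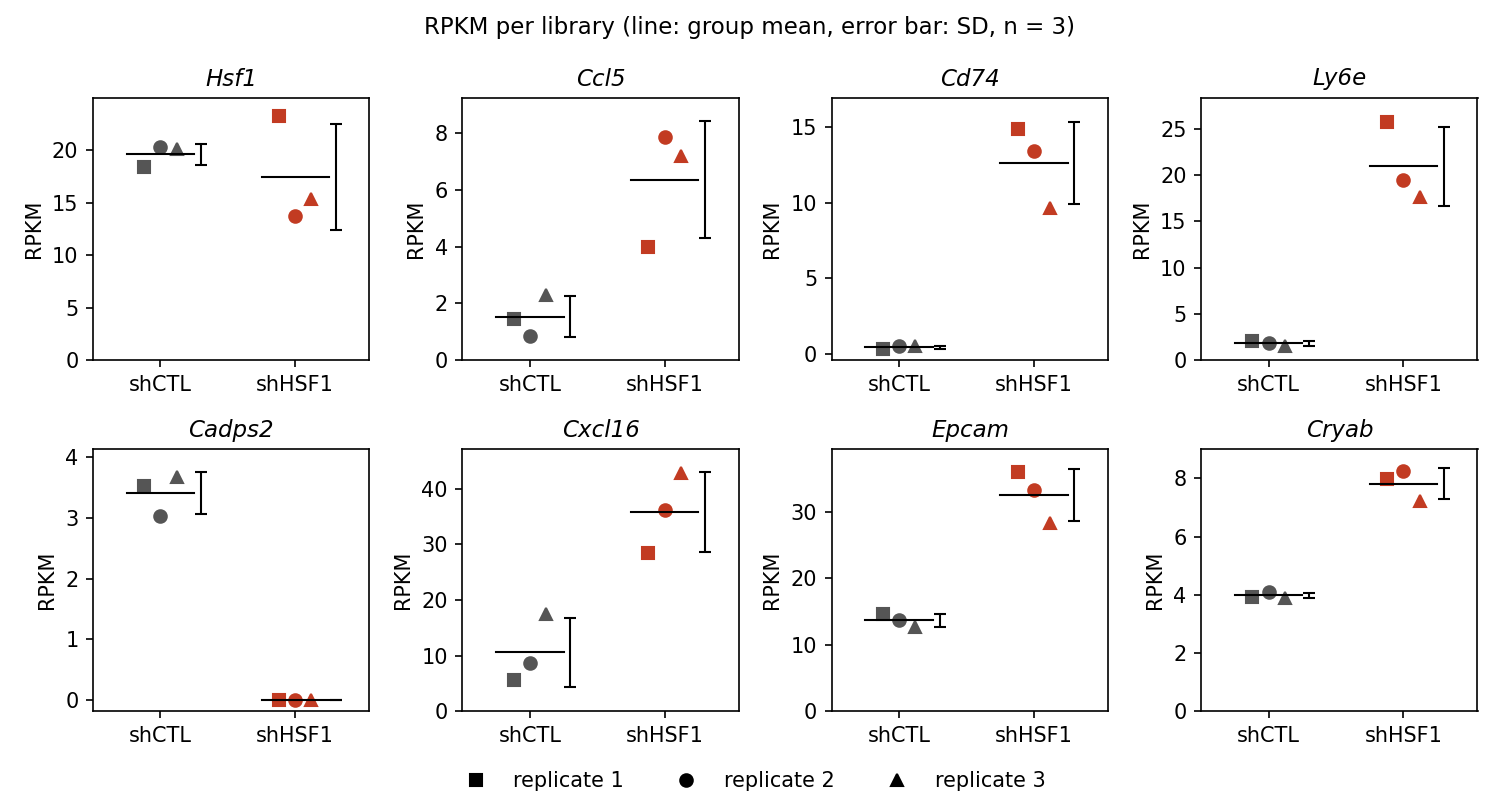
RPKM of 8 genes in each library; the vertical axis of each panel is RPKM, markers show the replicate number, lines the group means and error bars the SD (n = 3). Hsf1 stood highest, at 23.2 RPKM, in the library labelled shHSF1 replicate 1, while Cd74 and Ly6e were higher in all 3 libraries labelled shHSF1 and Cadps2 was at 0 in them.

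Across all genes tested, 3 passed an adjusted p of 0.05 in limma, and each differed in all 3 pairs, replicate 1 included. Cd74, the invariant chain that guides MHC class II molecules, rose from 0.439 ± 0.107 to 12.7 ± 2.71 RPKM (SD, n = 3; log2 difference 3.79, SE 0.22, adjusted p = 0.00748). Ly6e, an interferon-inducible protein anchored in the cell membrane, rose from 1.86 ± 0.269 to 20.9 ± 4.27 RPKM (log2 difference 3.17, SE 0.20, adjusted p = 0.00748). Cadps2, which takes part in the release of dense-core vesicles, fell from 3.41 ± 0.341 RPKM (525, 434 and 603 reads) to 0 reads in each library labelled shHSF1. With a floor of 3 reads per library, that is at least 168-fold lower (adjusted p = 0.00748). In the replicate 1 pair alone the log2 differences were 4.24 for Cd74, 3.34 for Ly6e and −3.01 for Cadps2. The count moved with single libraries left out: it was 0 without shCTL replicate 2 and 0 without the library labelled shHSF1 replicate 2 (771 and 778 genes at an unadjusted p under 0.05), 1 without shHSF1 replicate 3, 2 without shCTL replicate 1, 5 without shCTL replicate 3 and 8 without the library labelled shHSF1 replicate 1. Over those fits the log2 differences stayed between 3.67 and 3.97 for Cd74, 3.02 and 3.29 for Ly6e, and −3.04 and −2.91 for Cadps2. At an unadjusted p under 0.05 the 6 libraries gave 1296 genes, and in 2279 genes (20.0%) the groups did not overlap, 1464 of them higher and 815 lower in shHSF1. For 6 exchangeable libraries chance gives 10%, and with replicate 1 apart in both groups these are not exchangeable.

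With the replicate number as a block, 20 genes passed (16 higher, 4 lower), among them the same 3. The block takes same-numbered libraries as pairs, which the data bear out for replicate 1 only. All but Ly6e (blocked limma adjusted p = 0.0285) had the same blocked adjusted p of 0.0494, just under the threshold. Ifi47, an interferon-inducible GTPase, stood at 0.599 RPKM in shCTL and 5.39 in shHSF1 (log2 difference 2.41, blocked adjusted p = 0.0494), and Gsdmd, the pore-forming protein of pyroptosis, at 8.28 and 22.2 RPKM (log2 difference 1.37). Epcam, an epithelial adhesion molecule, rose from 13.7 to 32.5 RPKM (log2 difference 1.21), and Atp1b1, a subunit of the sodium pump, from 19.0 to 43.3 RPKM (1.16). The tubulin genes Tubb2a (6.95 to 23.9 RPKM) and Tubb2b (0.365 to 6.78 RPKM) also passed; they are close copies, and how shared reads were assigned is not given in the sources used here. Mmp10, a matrix protease, differed by 2.18, the protease Prss12 by 2.90, the myosin Myo7a by 2.06, the kinase scaffold Akap12 by 1.94 and the matrix-associated Wisp1 by 1.57, while Mfap3l, Ubash3b and Cdc42ep5 differed by 2.03, 1.85 and 1.82. Lower were Tenm4, a transmembrane protein of the teneurin family (7.21 to 1.46 RPKM, log2 difference −1.98), Dmp1, a phosphoprotein of mineralised matrix (−1.98), and Phtf1 (−1.06). These genes were chosen after their values were seen. Without the block the limma adjusted p was 0.359 for Mmp10 and 0.388 for Dmp1, whose values overlapped between the groups. With each library left out in turn, Mmp10 ran from 1.38 to 2.76 and Dmp1 from −2.59 to −1.29. Without both replicate 1 libraries 1262 genes passed (802 higher, 460 lower), and with replicate 1 as a batch covariate 642 did (443 higher, 199 lower). Both sets held all 20.

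Of 24 gene lists fixed before the data were examined, 6 passed camera with a preset inter-gene correlation of 0.01. The interferon-gamma-induced list was higher in shHSF1 (median log2 difference 0.62 over 19 tested members, 17 of them above 0, adjusted p = 5.34e-05; adjusted p = 0.783 with an estimated correlation). With no filter on low values its median over 26 members was 0.35 (adjusted p = 3.79e-05; adjusted p = 0.749 with an estimated correlation). Of its members Cd74 passed over all genes, and 5 passed adjusted over the list alone: Cd74, the GTPases Tgtp1 (0.0649 to 1.19 RPKM) and Irgm1, and the transcription factors Irf1 and Irf8. The MHC class I antigen presentation list (median 0.43, 20 members, 16 above 0, adjusted p = 0.0021; adjusted p = 0.783 with an estimated correlation) had no member past the test over all genes and 2 adjusted over the list alone, the proteasome activator subunit Psme1 (72.9 to 129 RPKM, log2 difference 0.81) and Irf1 (0.80); the class I genes H2-K1 and H2-D1, which resemble each other closely, had 0.46 and 0.41, and B2m −0.17. Without shCTL replicate 2 the MHC class I median was 0.23 (adjusted p = 0.0404; adjusted p = 0.820 with an estimated correlation). The type I interferon-stimulated list (median 0.36, 32 members, 26 above 0, adjusted p = 0.00168; adjusted p = 0.917 with an estimated correlation) had none passing either way; Oas1a, which senses double-stranded RNA, and Trim25 had log2 differences of 1.19 and 0.58. With the replicate block the members passing adjusted over the list alone were 8 for the interferon-gamma list, 4 for MHC class I and 4 for the type I list, all higher. In the pairs of replicates 1, 2 and 3 the medians were 0.62, 1.09 and 0.51 for the interferon-gamma list, 0.16, 0.80 and 0.24 for MHC class I, and 0.16, 0.63 and 0.24 for type I genes. Without both replicate 1 libraries all 3 were called (adjusted p between 0.000149 and 0.000286), with 5, 7 and 8 members passing over all genes, all higher. With an estimated correlation none was (adjusted p = 0.926 for each), but that version has little power with so few libraries.

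The chemokine list was higher in shHSF1 (median log2 difference 1.76 over 11 tested members of 36 in the file, 10 above 0, camera adjusted p = 0.0021; adjusted p = 0.783 with an estimated correlation). With no filter on low values the median over 24 members was 0.23, 20 of them above 0 (adjusted p = 0.0303; adjusted p = 0.749 with an estimated correlation). No member passed over all genes, and 4 did adjusted over the list alone: Ccl5, Ccl20, the membrane-bound chemokine Cxcl16 (5.59, 8.72 and 17.4 RPKM in shCTL, 28.4, 36.1 and 42.7 in shHSF1) and Cx3cl1. With the replicate block 8 did, 7 higher and 1 lower. The spread within groups was wide. Ccl2, which attracts monocytes, stood at 3.63, 3.24 and 136 RPKM in shCTL and at 9.37, 116 and 227 RPKM in shHSF1, and the neutrophil attractants Cxcl1 and Cxcl5 stood at 99.0 and 96.5 RPKM in shCTL replicate 3 against 8.43 RPKM or less in shCTL replicates 1 and 2. The NF-kB target list, which shares Ccl2, Ccl5, Ccl20 and Cxcl1 with it, was also higher (median 0.61, 27 members, 22 above 0, adjusted p = 0.0021; adjusted p = 0.917 with an estimated correlation) with no member passing either way; Rel, a subunit of NF-kB, had a log2 difference of 0.75. Without shCTL replicate 2 the NF-kB call was lost (median 0.44, adjusted p = 0.0845), and without shCTL replicate 3 the median was 0.92 (adjusted p = 5.59e-10; adjusted p = 0.375 with an estimated correlation). Pair medians were 1.2, 2.61 and 0.74 for chemokines and 0.39, 1.14 and 0.24 for NF-kB targets. Both lists were called without the replicate 1 libraries (adjusted p = 0.0112), with 4 and 2 members passing over all genes, all higher. With an estimated correlation neither was (adjusted p = 0.926 for both).

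The G2/M cell cycle list was lower over the 6 libraries (median −0.33, 31 members, 29 below 0, adjusted p = 0.0021; adjusted p = 0.989 with an estimated correlation), with no member passing. The difference lay in the replicate 1 pair, whose median was −0.92, against −0.13 and 0.022 in pairs 2 and 3. The mitotic genes Cenpf and Cenpe had log2 differences of −0.67 and −0.50. With each library left out in turn these ran from −0.96 to −0.22 and from −0.74 to −0.063. Without the library labelled shHSF1 replicate 1 the median was 0.20 (adjusted p = 0.0942), without shCTL replicate 2 −0.13 (adjusted p = 0.0999), and without both replicate 1 libraries −0.056 (adjusted p = 0.544).

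**Figure D3:**
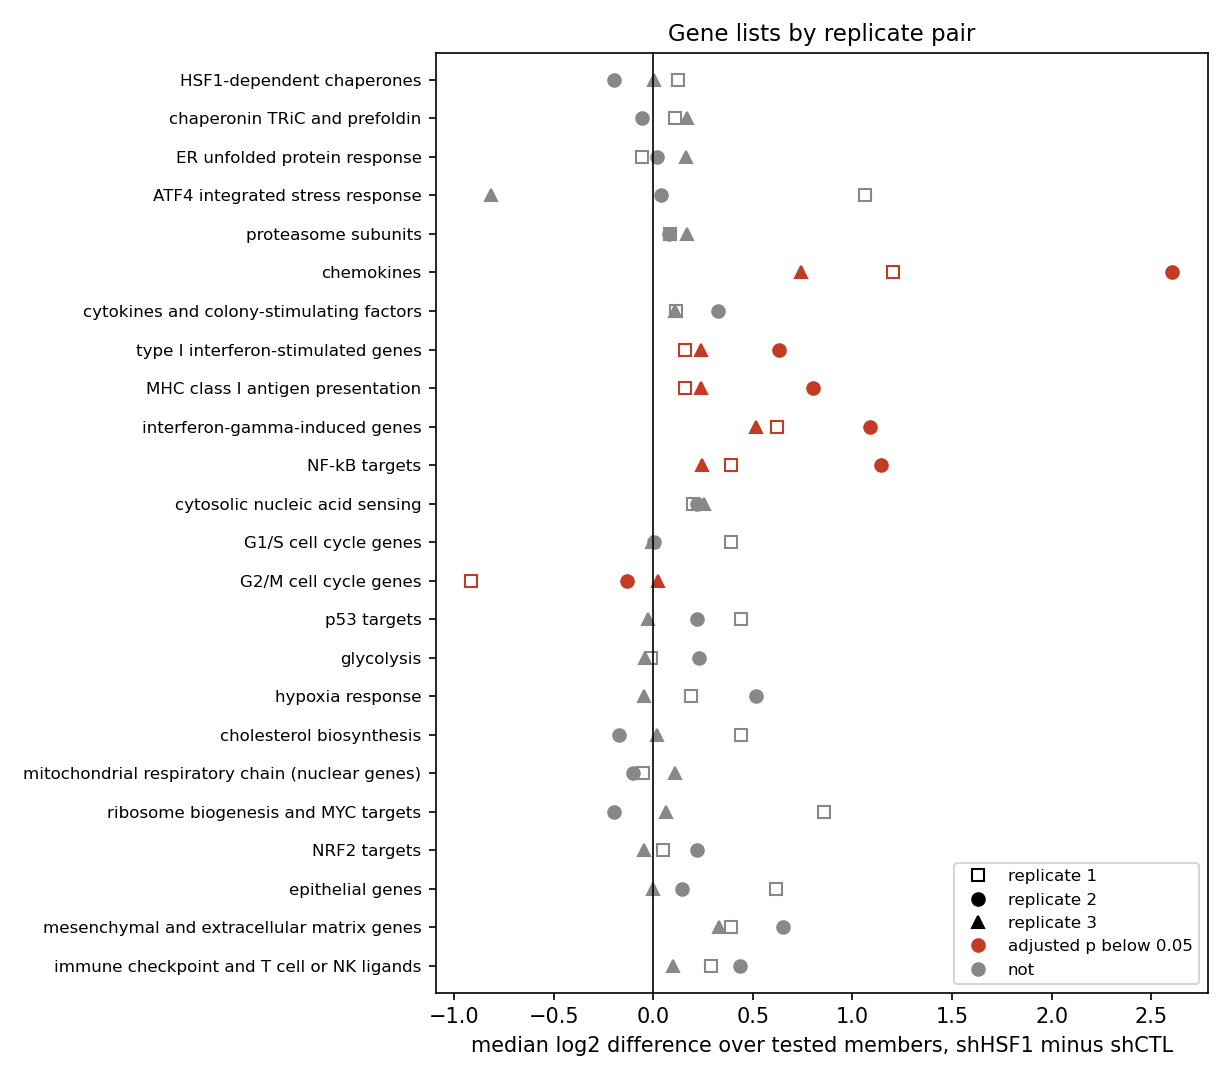
Median log2 difference (shHSF1 minus shCTL) over the tested members of each of 24 gene lists, one marker per replicate pair; red lists passed camera at an adjusted p of 0.05 over all 6 libraries. The G2/M medians run from −0.92 in pair 1 to 0.022 in pair 3, and the interferon-gamma medians lie between 0.51 and 1.09.

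The list of HSF1-dependent chaperones did not pass (median log2 difference −0.046, mean 0.0047, 30 members, 12 above 0, adjusted p = 0.455; pair medians 0.12, −0.20 and 0.0052). The abundant cytosolic chaperones Hspa8 and Hsp90ab1 had log2 differences of 0.078 and −0.010. Dnaja1, a co-chaperone of Hsp70, had −0.44 (SE 0.14, adjusted p = 0.314), and Hspb1 was at 0 in all 6 libraries. Whether the Hspb1 transcript is absent or its reads went uncounted cannot be told, since the treatment of shared reads is not given. Cryab, a small heat shock protein, was the 1 member past the test adjusted over the list alone and was higher in shHSF1, at 3.98 ± 0.0964 against 7.82 ± 0.533 RPKM (SD, n = 3; log2 difference 0.89, adjusted p over all genes 0.112). Without both replicate 1 libraries the list was not called (median −0.10, adjusted p = 0.163), and 3 members passed over all genes. Dnaja1 (−0.57, SE 0.10, adjusted p = 0.0308) and Zfand2a (−0.60, SE 0.11, adjusted p = 0.0312) were lower and Cryab (0.87, SE 0.12, adjusted p = 0.0182) higher. The list was called lower without shCTL replicate 1 (median −0.19, adjusted p = 0.0154, and adjusted p = 0.827 with an estimated correlation). Without the library labelled shHSF1 replicate 1 it was not called (median 0.024, adjusted p = 0.989). Its members were lower in replicate 1 than in the other replicates (medians −0.35 in shCTL and −0.12 in shHSF1). Leaving out shCTL replicate 1 keeps that difference in shHSF1 alone, which moves the list down. The call without shCTL replicate 1 thus cannot be told apart from the replicate 1 difference.

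The other 17 lists had adjusted p between 0.130 and 0.982: chaperonin TRiC and prefoldin, ER unfolded protein response, ATF4 integrated stress response, proteasome subunits, cytokines and colony-stimulating factors, cytosolic nucleic acid sensing, G1/S cell cycle, p53 targets, glycolysis, hypoxia response, cholesterol biosynthesis, mitochondrial respiratory chain, ribosome biogenesis and MYC targets, NRF2 targets, epithelial genes, mesenchymal and extracellular matrix genes, and immune checkpoint and T cell or NK ligands. For the ER, ATF4 and NRF2 lists the median and mean were above 0 while camera, which compares a list with other genes, gave a lower direction. Members passing adjusted over the list alone were 2 higher and 1 lower for cytokines (5 and 3 with the replicate block), 4 and 0 for the mesenchymal list (9 and 1), 2 and 1 for the immune checkpoint list (5 and 1), 4 and 1 for epithelial genes (5 and 2), 2 and 1 for nucleic acid sensing (1 and 1). For hypoxia none passed (4 and 1 with the block), nor for NRF2 targets (4 and 3). Values in the libraries labelled shHSF1 were higher without passing over all genes for the cytokine Il1a (log2 difference 3.94, SE 0.70, adjusted p = 0.149), the matrix protein Postn (2.69, SE 0.56, adjusted p = 0.178), the cell cycle inhibitor Cdkn1a (1.61, SE 0.35, adjusted p = 0.184), the immune ligand Lgals9 (1.17, SE 0.19, adjusted p = 0.112), the splicing regulator Esrp1 (0.266 and 1.26 RPKM, adjusted p = 0.116), and Tmem173, the adaptor STING (0.67, SE 0.14, adjusted p = 0.178). Ftl1, the ferritin light chain, stood at 1476 RPKM in shCTL and 913 in shHSF1 (−0.68, SE 0.18, adjusted p = 0.238). Further genes named by the rule had log2 differences of 1.28 (the growth factor Tgfb2), 1.18 (Pvrl2, a ligand of T and NK cell receptors), 0.64 (the basement membrane collagen Col4a2), 0.54 (the proteasome subunit Psmb6), 0.42 (the ER co-chaperone Dnajc3), 0.39 (the chaperonin subunit Cct4) and 0.23 (the replication licensing factor Cdt1), none passing over all genes. With replicate 1 as a batch covariate all of these genes passed (adjusted p between 0.0158 for Tgfb2 and 0.0478 for Cdkn1a) except Cdt1 (adjusted p = 0.151). Most of the other genes that the rule named from these lists did not. Among them were Slc7a11 (adjusted p = 0.479), Ebp (0.324), Atf3 (0.286), Tm7sf2 (0.186) and Sdha (0.114). Epcam (0.0128), Pfkm (0.0381), Bnip3l (0.0439) and Ero1l (0.0480) passed. With the replicate block none of the genes named in this paragraph passed except Epcam (adjusted p = 0.0494). The mesenchymal list was called without both replicate 1 libraries (median 0.50, adjusted p = 0.010), where 9 of its members rose. With an estimated correlation it was not called (adjusted p = 0.926).

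Markers of other cell types were mostly at or near 0. The median over the listed genes of T and NK cells and of endothelial cells was 0 RPKM in each library, that of macrophages and other leukocytes at most 0.0308 RPKM, and that of fibroblasts at most 0.0733 RPKM. These lists were not tested in the main fit, since at most 2 genes of any of them passed the filter. With no filter on low values camera called none of them. The adjusted p was 0.215 for macrophages and other leukocytes (9 of 12 members above 0) and 0.215 for fibroblasts (7 of 10). It was 0.923 for T and NK cells (3 of 5) and 0.466 for endothelial cells (2 of 6). Cd14, a receptor of macrophages that other cells also make, was detected in every library and stood higher in all 3 libraries labelled shHSF1, as did Postn, which is on the fibroblast list; Cd14 was at 2.62, 2.89 and 3.55 RPKM in shCTL and at 6.49, 7.85 and 7.27 RPKM in shHSF1 (log2 difference 1.14, limma adjusted p = 0.112 over all genes and 0.0165 with the batch covariate).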

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

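The test of library depth and the test of the interferon-gamma list in the replicate 1 pair were chosen only after the results were seen, and the gene length test was recoded after its first run. The log2 difference of Hsf1 was 0.32 in the replicate 1 pair and −0.46 in replicates 2 and 3, which lie 0.78 apart. The limma interaction term did not pass (adjusted p = 0.0752 over all genes). Replicate 1 has 1 library per group and is assumed there to vary like replicates 2 and 3.

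Hsf1 was not lower in the library labelled shHSF1 replicate 1. A swap of the 2 replicate 1 labels is argued against, since 78.0% of the 1262 genes called from replicates 2 and 3 alone went the same way in replicate 1 (984 genes), where a swap would put most of them the other way. Control cells in that library are argued against too: the median difference in replicate 1 along the called direction was 60.3% of that in replicates 2 and 3. Open are a loss of knockdown in a culture that had carried the hairpin, and a transcript level that does not follow HSF1 protein, which was not measured here.

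Both replicate 1 libraries stood apart from the other 4, with a mean correlation of 0.930 to those 4 against 0.978 among them, a gap of 0.0481. Depth is argued against as the cause, because after random thinning of every library toward the lowest total (23750025 reads) the gap was 0.0477. A trend on gene length, as RNA quality can leave, is argued against, since 99.7% of the gap was left once it was removed (25.7% with the first coding, which added each gene's mean level to values that already held it). Replicate 1 cultures made up mainly of T or NK cells, other leukocytes, fibroblasts or endothelial cells are argued against by their marker lists. The highest median of such a list in a replicate 1 library was 0.0425 RPKM. These medians cannot show a minority of such cells, and other cell types, such as another epithelial line, had no list. A difference of day, passage or growth state stays open, since the labels give no meaning to the replicate number. Cell cycle lists were lower in replicate 1 in shCTL and shHSF1 (medians −1.92 and −1.42 for G1/S, −0.85 and −1.72 for G2/M). Camera called both with the preset correlation and neither with an estimated one (adjusted p = 0.865). That comparison was made after the data were seen and cannot tell day, passage and growth state apart.

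Cd74 was higher in the libraries labelled shHSF1. The interferon-gamma, MHC class I and type I interferon lists were called higher by camera with its preset correlation. With an estimated correlation none of these lists was called (adjusted p = 0.783, 0.783 and 0.917), though that version has little power with so few libraries. Macrophages in those cultures are argued against as the source. The median over Ptprc, Laptm5, Tyrobp, Fcer1g, C1qa, C1qb, C1qc and Lyz2 was 0.0120 RPKM (highest mean 0.619), against 12.7 RPKM for Cd74. Most of these genes are macrophage genes, so their median cannot speak for leukocytes that lack them, such as B cells. Whether the difference follows the Hsf1 mRNA level of each library cannot be told apart: in the replicate 1 pair, where Hsf1 was not lower, the interferon-gamma list had a median difference of 0.62 with 14 of 19 members higher, but its lower quartile was −0.037. Cd74 and Ly6e had log2 differences of 4.24 and 3.34 in that pair, against 3.80 and 3.06 in pair 2 and 3.35 and 3.13 in pair 3, but 1 library per group keeps the question open. An effect of lower HSF1, named by the design, and differences between the cell populations carrying each hairpin both stay open.

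For the count of 3 changed genes, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave as many, and the highest other gave 2 genes. For the 6 changed gene lists, 10 of 10 splits gave as many, and the highest other gave 13. With 10 splits a share under 0.05 cannot be reached. Among the 4 splits that part all 3 pairs, the other 3 called 0 genes each and 13, 8 and 10 lists. With the replicate block the real split called 20 genes and 6 lists, and those 3 called 0 genes and, in the same order, 14, 12 and 13 lists. Camera with its preset correlation thus called at least as many lists for arbitrary splits, which points to genes of a list moving together between these libraries whatever their group.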

How the results depend on the processing

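Alternatives chosen after the data were seen are those without both replicate 1 libraries, with the batch covariate and with voom. The count of 3 genes was within 1.5 times of the reported value in 8 of 21 alternatives and otherwise moved: 18 with no filter on low values, 22 with no variance trend, 5954 with library weights (the weights did not converge and ran from 0.123 to 8.70), 20 with the replicate block, 0 to 8 with each library left out, 1262 without both replicate 1 libraries, 642 with the batch covariate, 11 with voom on whole reads and 106 with voom and the replicate block. Quantile normalization called 2 genes higher and 2 lower. Hsf1 kept its sign in all 20 alternatives (−0.51 to −0.049; −0.049 to −0.42 with each library left out) and passed in 2: −0.51 with library weights and −0.46 without both replicate 1 libraries. Ccl5 kept its sign in all 20 (1.5 to 2.46; 1.5 to 2.03 with each library left out) and passed in 3: 2.46 with library weights, 2.03 without both replicate 1 libraries and 1.76 with the batch covariate. The 6 lists became 0 with an estimated correlation (0 at an unadjusted p under 0.05), 0 with fry (5 at an unadjusted p), 10 with quantile normalization and 5 to 11 with each library left out. The other filters, the fit with no variance trend, the batch covariate and the block left Hsf1 and Ccl5 at log2 differences of −0.20 and 1.76. Those fits cannot change these differences, so they do not test the sign. The block called the same 6 lists and no other. With an estimated correlation it called none of them (adjusted p = 0.941 for each), which says little with so few libraries. Of 1805 values for named genes and lists, 1560 stayed on their side of the threshold, 212 passed newly, 26 no longer passed and 7 reversed. A list counted as reversed only if either fit called it. Among the 1560 were 62 values of lists that neither fit called and whose direction or median turned. Without both replicate 1 libraries these were, among others, cholesterol biosynthesis (0.20 to −0.032), ribosome biogenesis (0.20 to −0.043) and the ATF4 median (0.092 to −0.49). Reversed without shCTL replicate 1 were Cdt1 (−0.031 to 0.42 over the libraries left out), Cdc6 (−0.29 to 1.44), and the lists of G1/S (−0.42 to 0.63), cholesterol biosynthesis (−0.29 to 0.43) and ribosome biogenesis (−0.18 to 0.43). Reversed without shCTL replicate 3 was the ATF4 list by camera direction (−0.18 to 0.57), and without shHSF1 replicate 1 the G2/M list (−0.62 to 0.20). The G1/S, cholesterol, ribosome biogenesis and G2/M lists were lower in replicate 1 than in replicates 2 and 3 of either group. Their medians in shCTL and shHSF1 were −1.92 and −1.42, −1.24 and −0.81, −1.40 and −0.32, and −0.85 and −1.72. Leaving out 1 replicate 1 library keeps that offset in the other group alone, which moves these lists the way they turned. Beyond that and fewer libraries the cause was not tested, nor was it for the ATF4 list. Symbols shared by several genes were not summed, since the dates stood for different genes, and the alternatives planned for a deposited table of raw counts were not run, since the file holds RPKM. Ccl5 in shCTL rested on 11 to 33 reads, which limits its ratio.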

Other observations

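The comparison of replicate 1 with replicates 2 and 3 was made after the data were seen. Allowing for group, 4051 genes passed limma (2383 higher and 1668 lower in replicate 1), among them 2 lower genes chosen after their values were seen: Tk1, a thymidine kinase, stood at 20.6 and 24.2 RPKM in replicate 1 against 73.4 to 90.0 RPKM elsewhere (log2 difference −1.83, SE 0.08), and Rrm1, a subunit of ribonucleotide reductase, at 28.0 and 28.3 against 88.8 to 110 RPKM (−1.82, SE 0.10). In shCTL and shHSF1 respectively, the median log2 difference was −1.92 and −1.42 for the G1/S list, −0.85 and −1.72 for the G2/M list, −1.24 and −0.81 for cholesterol biosynthesis, −1.40 and −0.32 for ribosome biogenesis and MYC targets, and −0.49 and −0.41 for proteasome subunits. These 5 lists passed camera (the highest adjusted p was 5.26e-08; adjusted p = 0.865 for each with an estimated correlation). Another 5 of the 24 passed: HSF1-dependent chaperones (−0.35 and −0.12, adjusted p = 0.0069), chaperonin TRiC and prefoldin (−0.30 and −0.25, adjusted p = 0.0138), glycolysis (−0.090 and −0.48, adjusted p = 0.0168) and the respiratory chain (−0.18 and −0.049, adjusted p = 0.0168) were lower, and type I interferon-stimulated genes (0.48 and 0.19, adjusted p = 0.0195) higher. With an estimated correlation none of these was called (adjusted p = 0.865 or 0.869).

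The interleukin and chemokine genes with the widest spread within shCTL shared 1 library: Ccl2, Ccl7, Cxcl1, Cxcl5, Ccl20 and Il1a stood at 136, 9.54, 99.0, 96.5, 7.07 and 4.48 RPKM in shCTL replicate 3, and at no more than 3.63, 0.152, 8.43, 4.70, 0.203 and 0.350 RPKM in shCTL replicates 1 and 2. They were chosen after their values were seen.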
